A study of Mus musculus with 11 samples.

How the data were processed

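The series holds 11 samples of mouse mammary tumour cells, each measured on 1 Affymetrix expression array from biotin-labelled cRNA made of total RNA. The labels put 4 arrays in the primary tumour group, 3 in the residual lesion group, taken 28 days after doxycycline withdrawal, and 4 in the recurrent tumour group. They do not say that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. No scanner files were used here.

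The authors deposited 1 table of log2 signals with 24479 rows, 1 probe set per Entrez Gene identifier, and 11 columns, each named by its sample's identifier. Sample titles gave the group and replicate number. The values were made with RMA, which corrects background, normalizes across arrays and summarises probes on the log2 scale, and with R 3.0.2, per the submitters' processing notes. The version of the redefined probe annotation is not given in the sources used here. The log2 values ran from 1.10 to 13.3 and were used as deposited. RMA compresses differences between dim signals, so fold changes of genes near the lowest levels may be understated. Beside levels, the olfactory receptor genes of each array (1066 genes) give the range in which a signal cannot be told from background.

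Gene names came from the platform's probe table. Of the probe sets 23281 had 1 symbol, none had several, and 1198 were absent from that table, of which 556 were named through their Entrez Gene identifier in the reference table of assembly GRCm38.p6. The other 642 had no name here and were tested apart from the named genes. A pair of symbols each had 2 probe sets, of which the brighter was kept, leaving 23835 genes. That assembly also gave the order of neighbouring genes, and no coordinates are reported.

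Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 3 groups was fitted to all 11 arrays, with 8 residual and 3.46 prior degrees of freedom, and moderated two-sided tests were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called at an adjusted p under 0.05. Reverting genes were those called in residual against primary cells and called with the opposite sign in recurrent against residual cells. Overlaps of comparisons that share arrays were set beside the overlap of independent lists and beside 100 simulations of unchanged groups.

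Gene lists of pathways and cell types, 43 with at least 5 measured members, were tested with camera at its preset correlation of 0.01 and adjusted over the lists of each comparison. Of 1133 list entries, Y-linked genes included, 1103 were measured. A list's median and mean are those of the log2 fold changes of its members, and its members were also counted after adjustment over the list alone. The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. Which lists the text describes member by member was decided after their results were seen.

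The rule named Wnt1 in every sample first. For each comparison it then took the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out predicted, unnamed, olfactory and vomeronasal receptor genes. Of each list described it took up to 4 called members with the largest change, or up to 2 with the smallest p where none was called, and for markers of other cell types also the 3 members with the highest mean. Genes named outside this rule are said to be so, and some genes that the rule took are not reported here.

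The steps were tested on simulated data with 200 of 23835 genes changed. For residual against primary cells 58% of genes changed 2-fold and 94% of those changed 4-fold were recovered with 4 false calls, for recurrent against primary cells 66% and 98% with 9, and for recurrent against residual cells 57% and 97% with 3. A list shifted as a whole was called in each, and 0 unshifted lists were. Genes were simulated independently of each other, so false list calls from members that vary together could not show. In the measured data the correlation within the macrophage and monocyte list, for example, was estimated at 0.58.

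Alternatives were a fit on only the groups compared, the replicate number as a block, arrays centred on their medians, a second quantile normalization, filters on dim genes, other ways to join probe sets, other estimates of the spread, stricter thresholds, leaving out each array in turn, and for lists an estimated correlation, fry and camera on ranks. A filter that kept the 13712 genes above the 95th percentile of olfactory receptor genes on at least 3 arrays, and scaling of arrays to one median and interquartile range, were added after the data had been seen. Array weights used statmod 1.5.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.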

Results

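RNA was measured in tumour cells taken from mice at 3 stages of a mammary cancer driven by Wnt1, a secreted ligand of the Wnt pathway. The cells carry MMTV-rtTA and TetO-Wnt1, a pair of transgenes through which doxycycline switches Wnt1 on in mammary epithelium. They were marked with H2B-eGFP, a green fluorescent histone, were grown orthotopically in female nu/nu mice, a strain without a thymus, and were isolated again as cells labelled positive for the fluorescent protein. The mice received doxycycline, and its withdrawal was used to switch the oncogene off. There were 4 arrays of primary tumour cells, 3 arrays of cells from residual lesions 28 days after withdrawal, and 4 arrays of recurrent tumour cells. Each array gave 1 log2 signal for 24479 probe sets, and 23835 genes with a name were tested. The median signal lay between 4.29 and 4.41 on every array. The interquartile range was 3.52 to 3.57 on the residual arrays, 3.73 to 3.81 on the primary arrays and 3.67 to 3.74 on the recurrent arrays. Pearson's r between arrays, across genes that are not independent of each other, was 0.983 to 0.989 within the primary group, 0.972 to 0.977 within the residual group and 0.968 to 0.980 within the recurrent group. Between groups it was 0.945 to 0.957 for residual and primary arrays, 0.965 to 0.977 for recurrent and primary arrays, and 0.951 to 0.966 for recurrent and residual arrays. The number of arrays limits the precision of every value given here.

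Wnt1 itself, the driving oncogene, read between 2.89 and 3.26 on all 11 arrays. The medians of 1066 olfactory receptor genes, a class that mammary cells are not known to use, were 2.33 to 2.54, and their 95th percentiles 3.96 to 4.38, so Wnt1 read inside the range of that class. Its level was 3.04 ± 0.04 in primary, 3.12 ± 0.10 in residual and 3.06 ± 0.15 in recurrent cells (mean ± SD, n = 4, 3 and 4). In limma it gave adjusted p values of 0.719, 0.963 and 0.823 for residual against primary, recurrent against primary and recurrent against residual. The part of the gene its probes match is not given in the sources used here and may lie outside the transgene, so this level checks nothing about induction. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty read 1.81 to 2.88 on every array.

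The first comparison asked how tumour cells that remained after withdrawal differed from cells of the primary tumours. Residual cells had lower levels of 46 of 47 genes of mitosis (camera, adjusted p = 8.1e-70). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 10.23 ± 0.32 to 5.13 ± 0.72 (log2 signal, mean ± SD, n = 4 and 3), and Anln, a scaffold of the cleavage furrow, from 9.46 ± 0.09 to 4.56 ± 0.61. Postn, the matrix protein periostin, went from 5.39 ± 1.14 to 12.18 ± 0.30, and Ogn, a small leucine-rich proteoglycan, from 2.73 ± 0.62 to 9.33 ± 1.19. Nkd2, an inhibitor of Dishevelled in the Wnt pathway, rose from 3.95 ± 0.28 to 9.91 ± 0.25, while Fosl1, a transcription factor induced by RAS-MAPK signalling, fell 25-fold. In limma, 2960 of 23835 genes passed at an adjusted p under 0.05, of which 1146 were higher and 1814 lower in residual cells. Centred on each array's median, 3232 genes passed, with 899 higher and 2333 lower, which moved the share of higher genes from 38.7% to 27.8%. Quantile-normalized again, 1149 were higher and 1404 lower, a share of 45.0%. Of the called genes 1361 differed at least 2-fold, 578 upwards and 783 downwards. The arrays of the groups did not overlap for 24.8% of genes, where chance gives 5.71%.

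**Figure D1:**
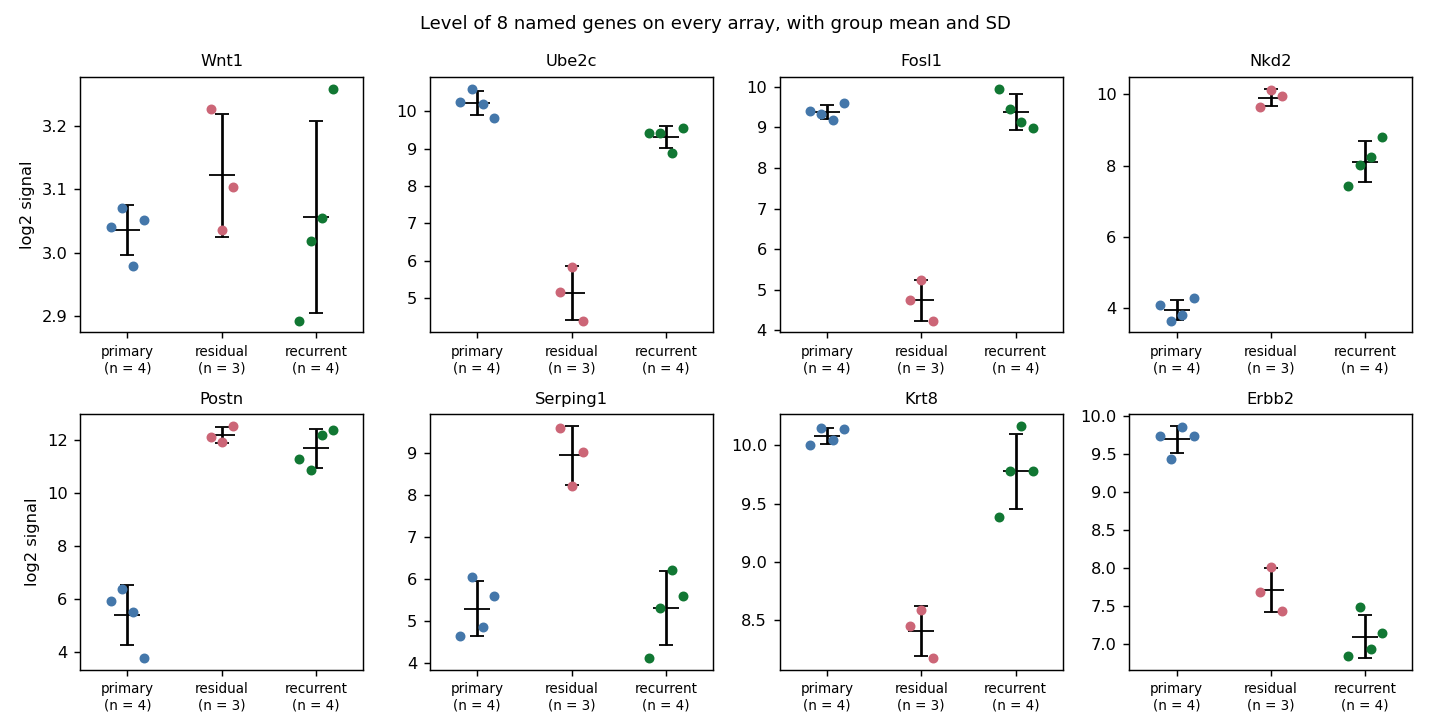
Level of 8 named genes on every array (log2 signal, a separate scale for each gene), with primary (n = 4), residual (n = 3) and recurrent (n = 4) arrays as points, the group mean as a horizontal bar and the SD as whiskers. Wnt1 stays between 2.89 and 3.26, the Ube2c, Fosl1 and Krt8 means are lowest in residual cells, Nkd2 and Postn lie above the primary arrays in residual and recurrent cells, Serping1 is high on the residual arrays alone, and Erbb2 lies below the primary arrays in residual and recurrent cells.

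The 10 largest rises with no overlap between arrays were those of Postn, Ogn, Fmod, Nkd2, Fam180a, Prelp, Comp, Apod, Aspn and Itgbl1, with log2 fold changes from 6.79 to 5.42 and adjusted p from 3.42e-07 to 0.00179. In primary cells the means of Aspn, Comp, Fam180a, Fmod, Itgbl1, Nkd2 and Ogn lay below 3.96 to 4.02, the 95th percentiles of olfactory receptor genes on those arrays, so their changes were measured from a background level and their order is uncertain. Fmod, Prelp and Aspn, like Ogn, belong to the small leucine-rich proteoglycans, and Comp is a matrix protein of cartilage and tendon. The 10 largest falls were those of Stfa3, Grem1, H2bc7, Ube2c, Anln, Htr1b, Fosl1, Rgs16, Ccnb2 and Il18rap, with log2 fold changes from -6.41 to -4.47. Grem1, a secreted antagonist of bone morphogenetic proteins, went from 8.94 ± 0.09 to 3.71 ± 0.37 (adjusted p = 1.04e-06). Rgs16, which shortens G-protein signalling, fell by 4.54 (SE 0.40, adjusted p = 3.11e-05). Stfa3 and the histone gene H2bc7 have near-identical copies in the genome, so which copy gave their signal is uncertain. Grem1, H2bc7, Htr1b, Il18rap and Stfa3 fell to a background level, with residual means below the 95th percentiles of olfactory receptor genes there (4.34 to 4.38).

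Genes of cell division were lower almost as a whole. Of the 47 measured genes of the G2/M and mitosis list, 46 fell and 1 did not pass, and all 47 fell when adjusted over the list alone. Its median log2 fold change was -3.04 (camera, adjusted p = 8.1e-70, and adjusted p = 0.00181 with an estimated correlation). The mean of this list was 4.57 ± 0.11 on the residual arrays and 7.59 ± 0.08 on the primary arrays. Ccnb2 and Ccna2, the cyclins B2 and A2 of the mitotic kinases, fell by 4.48 and 4.32 (adjusted p = 8.94e-07 and 5.55e-06). Among 44 genes of S phase and DNA replication, 39 fell and 5 did not pass (40 fell adjusted over the list alone), with a median of -1.32 (adjusted p = 1.58e-33, and 0.00181 with an estimated correlation). Mcm6, part of the replicative helicase, changed by -3.33 (SE 0.23), Rrm2, a subunit of ribonucleotide reductase, by -3.27, Gins2 by -3.07 and Uhrf1 by -2.93. The list of cell cycle inhibitors and quiescence genes was not called (adjusted p = 0.483, but 0.0424 with arrays scaled to one interquartile range, a setting chosen after seeing the data), with 6 of 26 members higher, 5 lower and 15 not passing (7 and 5 adjusted over the list alone). Its members moved apart: Cdkn1a, the inhibitor p21, fell by 2.12 (adjusted p = 2.8e-05), and Bhlhe41, a circadian repressor, rose by 1.84 (adjusted p = 0.000112).

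Ribosome genes were lower as well. The ribosome biogenesis and MYC target list had 29 of 40 members lower and 11 not passing (36 lower adjusted over the list alone), with a median of -0.88 (adjusted p = 1.12e-21, and 0.0167 with an estimated correlation). Nop56 and Nop2, nucleolar proteins that process ribosomal RNA, changed by -1.49 and -1.45, and Dkc1, the pseudouridine synthase dyskerin, by -1.30 (adjusted p = 0.000423, 0.000408 and 0.000536). Of 43 measured ribosomal protein genes 28 fell and 15 did not pass (30 fell adjusted over the list alone), with a median of -0.76 (adjusted p = 1.25e-13, but adjusted p = 0.0982 with an estimated correlation). Rps15 and Rps24, proteins of the small ribosomal subunit, fell by 2.71 and 2.02. Many ribosomal protein genes have pseudogene copies, and 19 of the 62 fixed members had no measured row.

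Feedback genes of FGF and RAS-MAPK signalling were mostly lower, with 14 of 24 members lower, 2 higher and 8 not passing (16 and 2 adjusted over the list alone) and a median of -0.92 (adjusted p = 2.45e-08, but adjusted p = 0.113 with an estimated correlation). Besides Fosl1, Ereg, the EGF receptor ligand epiregulin, fell by 3.79 (SE 0.45, adjusted p = 0.00027). Ccnd1, cyclin D1, fell by 3.65 (SE 0.30, adjusted p = 1.96e-05). Canonical Wnt target genes were not called as a list (adjusted p = 0.128): of 33 members 6 rose, 3 fell and 24 did not pass (7 and 3 adjusted over the list alone). Those that rose included Nkd2 and Fzd7, a Wnt receptor, which rose by 1.78 (adjusted p = 0.000101), while Ccnd1 and Lgr6, an R-spondin receptor, fell, the latter by 1.54 (adjusted p = 0.00345). Of 12 secreted Wnt inhibitors 2 rose, 1 fell and 9 did not pass, the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.204). Sfrp2, a secreted decoy for Wnt ligands, rose by 1.53 (adjusted p = 0.000827), and Dkk2, an antagonist of the co-receptor Lrp6, fell by 1.36 (adjusted p = 0.00674).

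Fibroblast markers rose in residual cells, with 14 of 22 members higher and 8 not passing (15 higher and 1 lower adjusted over the list alone). Their median log2 fold change was 2.33 (adjusted p = 4.4e-12, but adjusted p = 0.0639 with an estimated correlation). Dpt, the matrix protein dermatopontin, went from 4.53 ± 0.52 to 9.61 ± 1.03 (adjusted p = 0.000309), and Lum, the proteoglycan lumican, from 3.64 ± 0.95 to 7.81 ± 1.08 (adjusted p = 0.00175). Serpinf1, a secreted serpin and among the brightest members, rose by 2.99 (SE 0.18, adjusted p = 1.92e-06). Mgp, an inhibitor of calcification and the brightest member, near the highest value of the table (13.34) where a rise would hardly show, was at 12.98 ± 0.04 in primary cells and at 13.15 ± 0.04 in residual cells (adjusted p = 0.358, but 0.00765 with arrays scaled to one interquartile range, a setting chosen after seeing the data). In primary cells 16 of the 22 fibroblast markers and 39 of the 45 matrix genes had a mean above 4.05, the median over the 11 arrays of the 95th percentile of olfactory receptor genes. Matrix genes followed, with 21 of 45 higher, 2 lower and 22 not passing (25 and 3 adjusted over the list alone) and a median of 0.80 (adjusted p = 1.62e-09, but adjusted p = 0.113 with an estimated correlation). Fbln5, an elastic fibre protein, rose by 4.75 (adjusted p = 7.1e-06), and Col3a1, a fibrillar collagen, by 4.00 (adjusted p = 0.000306). Of 24 genes of the TGF-beta pathway and its targets 11 rose, 1 fell and 12 did not pass (13 and 1 adjusted over the list alone), with a median of 0.73 (adjusted p = 1.69e-06, and 0.0167 with an estimated correlation). Ltbp2, a protein of the latent TGF-beta binding family, rose by 2.33, Smad6, an inhibitory Smad, by 2.18, Tgfb3 by 1.99 and Id3, a target of bone morphogenetic proteins, by 1.82.

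Pericyte markers were called with a small median of 0.28 (adjusted p = 0.0248, but adjusted p = 0.113 with an estimated correlation), and 1 of 9 members rose, also adjusted over the list alone: Pdgfrb, a receptor of platelet-derived growth factor that the fibroblast list also holds, from 7.67 ± 0.08 to 10.49 ± 0.21 (adjusted p = 5.74e-07). The pericyte call was lost with the values quantile-normalized again (adjusted p = 0.0607). Macrophage and monocyte markers were lower, with 9 of 28 members lower and 19 not passing (1 higher and 13 lower adjusted over the list alone) and a median of -0.90 (adjusted p = 2.27e-05, but adjusted p = 0.403 with an estimated correlation). Cd14, a co-receptor for bacterial lipopolysaccharide, went from 9.18 ± 0.23 to 7.72 ± 0.24 (adjusted p = 0.000901). Endothelial markers (2 of 23 higher, 1 adjusted over the list alone, median 0.03, adjusted p = 0.619) and lymphocyte and natural killer cell markers (1 of 24 higher, none adjusted over the list alone, median 0.05, adjusted p = 0.26) were not called.

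Epithelial markers moved in both directions. Of 27 luminal markers 4 rose, 4 fell and 19 did not pass (7 and 4 adjusted over the list alone), with a median of 0.63 and a mean of 0.20, and the list was not called (adjusted p = 0.0805) but was without residual 1 (0.0163) or residual 3 (0.0220), with arrays centred on their medians (0.0293) and by camera on ranks (0.00884). Scaling to one interquartile range, chosen after seeing the data, also gave a call (0.0348). The brightest members fell: Krt8 and Krt18, the simple-epithelium keratins, by 1.67 and 2.32, and Areg, the EGF receptor ligand amphiregulin, by 3.05 (adjusted p = 0.000103, 0.00432 and 3.82e-05). Basal and myoepithelial markers were not called (adjusted p = 0.18), with 3 of 24 higher and 2 lower, also adjusted over the list alone. Krt14, a basal keratin, rose from 7.63 ± 0.46 to 10.36 ± 0.30, and Itga6, an integrin that binds laminin, fell by 2.62 (adjusted p = 0.000286 and 0.000233). Milk protein genes were called with a median of 0.23 (adjusted p = 0.0444, but adjusted p = 0.123 with an estimated correlation). Of the 16 members 3 were higher and 1 lower (4 and 1 adjusted over the list alone). Csn2, beta-casein, rose from 2.76 ± 0.20 to 6.21 ± 1.34 (adjusted p = 0.000783). It read 5.04, 7.68 and 5.91 on residual 1, 2 and 3, and the mean of the luminal markers was 5.74 on residual 2 against 4.91 on the lowest residual array. The milk protein call was lost without residual 2 (adjusted p = 0.0719), primary 1 (0.0554), primary 2 (0.0629), primary 3 (0.0657) or recurrent 4 (0.0616), with the values quantile-normalized again (0.0727) and with the dimmest genes left out (0.110).

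Lists of glycolysis, hypoxia, cholesterol synthesis and oxidative phosphorylation genes were lower, each with a call that was lost when the correlation was estimated. Glycolysis genes fell in 10 of 17 cases (11 adjusted over the list alone, median -0.87, adjusted p = 8.24e-08, but adjusted p = 0.113 with an estimated correlation), among them Hk2, a hexokinase, at -1.98, Pfkl, a phosphofructokinase, at -1.97, and Tpi1 at -1.57. Hypoxia targets had 8 of 26 members lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 1.23e-05, but adjusted p = 0.285 with an estimated correlation), led by Egln3, an oxygen sensor, at -3.79 (adjusted p = 0.000765). Cholesterol synthesis genes had 9 of 23 lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 9.97e-07, but adjusted p = 0.325 with an estimated correlation), with Sqle, squalene epoxidase, at -1.94. For oxidative phosphorylation 14 of 57 genes fell (23 adjusted over the list alone, median -0.38, adjusted p = 7.56e-12, but adjusted p = 0.252 with an estimated correlation), by less than 1 log2 unit for Uqcrfs1, a subunit of respiratory complex III, at -0.84 and for Atp5g3 at -0.72.

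Complement and acute phase genes rose in 7 of 21 cases (8 adjusted over the list alone, median 0.97, adjusted p = 0.000294, but adjusted p = 0.113 with an estimated correlation). Serping1, the inhibitor of complement C1, went from 5.29 ± 0.65 to 8.94 ± 0.70 (adjusted p = 0.000637), and C1s1, a C1 protease, and Clu, the chaperone clusterin, rose by 2.11 and 1.37. Immediate early genes were called (median 0.35, adjusted p = 0.0247, but adjusted p = 0.526 with an estimated correlation). Of the 24 members 6 were higher and 1, Fosl1, lower (7 and 1 adjusted over the list alone). Egr2, a zinc finger factor, rose by 1.80 and Btg2, an antiproliferative gene, by 1.14 (adjusted p = 4.67e-05 and 0.00104). The immediate early call was lost without residual 1 (adjusted p = 0.0714), residual 3 (0.0730) or primary 2 (0.141). Among 21 Notch pathway genes, not called as a list (adjusted p = 0.0915), 5 rose, also adjusted over the list alone, including Jag1, a Notch ligand, at 2.77 and the co-activator Maml2 at 1.47. In all, 17 of 43 lists were called, 7 higher and 10 lower. The other 26 had adjusted p from 0.0805 to 0.904, and for 2 of these the median, mean and test differed in sign, as for none of the called lists. By fry, which does not compare a list with other genes, the lists of Wnt targets, secreted Wnt inhibitors, p53 targets, basal markers, mesenchymal transition, Notch, YAP and TAZ targets and receptor tyrosine kinases were called too (adjusted p from 0.00211 to 0.0351). Those of macrophage markers (0.0989) and immediate early genes (0.192) were not. Quantile normalization added YAP and TAZ targets (0.0103) and lysosome and autophagy genes (0.00164), and camera on ranks the interferon list (0.00863), which was also called without recurrent 3 (0.0487). Scaling to one interquartile range added these YAP and TAZ (0.0016) and lysosome lists (2.73e-05), Wnt targets (0.0424) and Notch genes (0.0423).

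**Figure D2:**
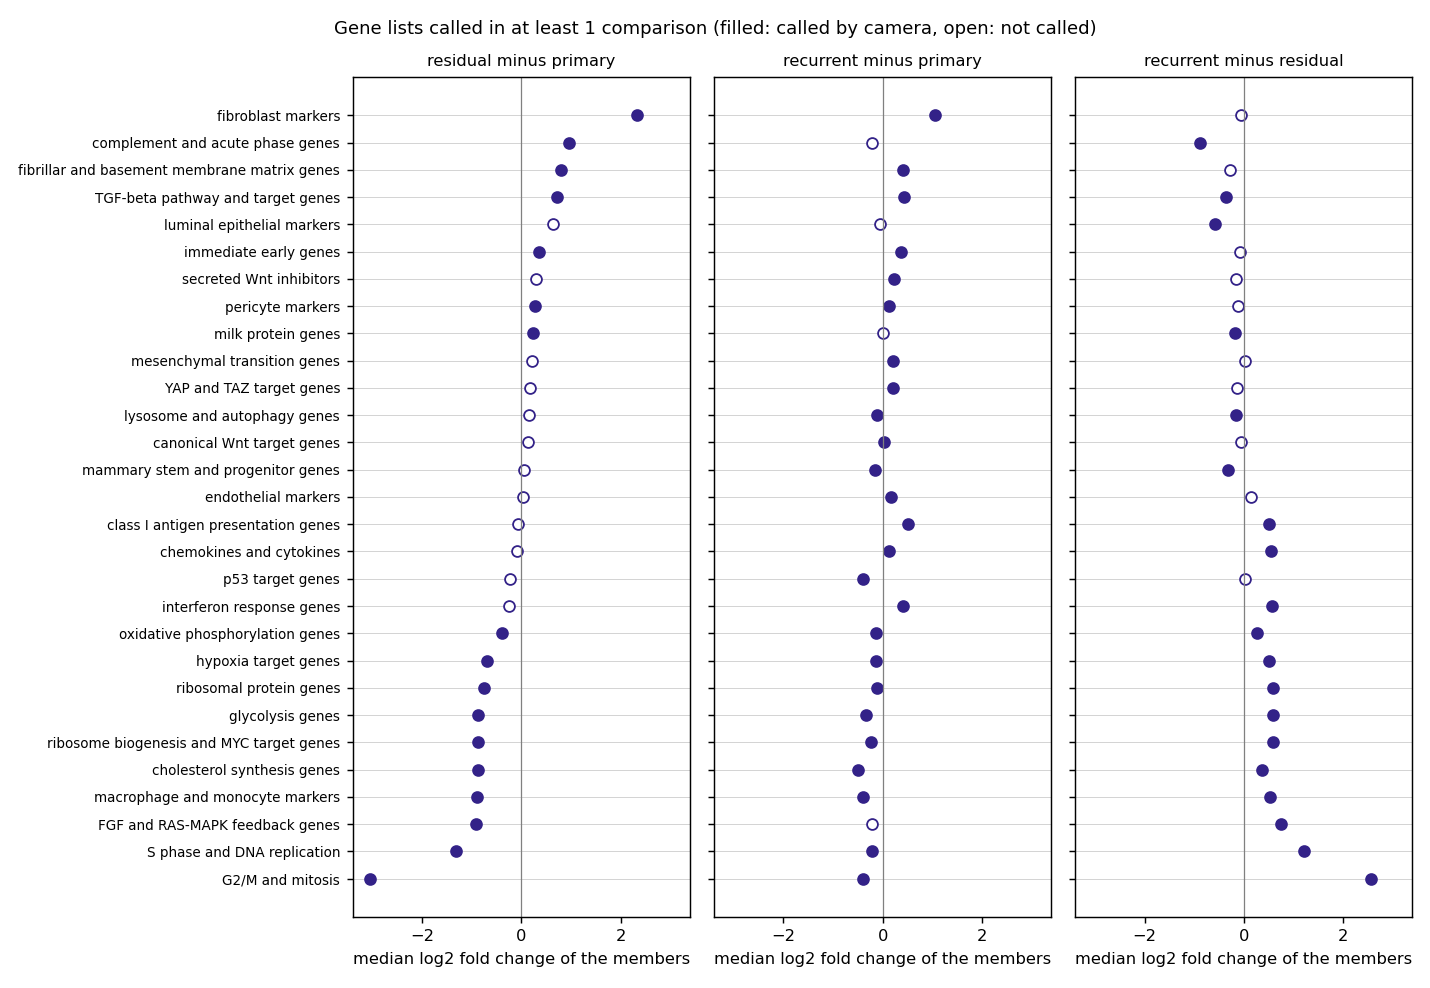
Median log2 fold change of the members of each gene list (x axis) called in at least 1 of the 3 comparisons (29 lists, y axis), 1 panel per comparison, filled where camera's adjusted p was under 0.05 and open where it was not. The G2/M and mitosis list runs from -3.04 in residual against primary cells to 2.56 in recurrent against residual cells, and fibroblast markers are filled on the right side in both comparisons with primary cells.

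The next comparison asked how recurrent tumour cells, grown back after withdrawal, differed from primary tumour cells. Ogn and Postn, high in residual cells, were high here too: Ogn went from 2.73 ± 0.62 to 9.70 ± 0.63 (n = 4 and 4), and Postn from 5.39 ± 1.14 to 11.68 ± 0.73. Mme, the membrane peptidase neprilysin, went from 5.27 ± 0.43 to 10.46 ± 0.22, a 36.4-fold rise. Erbb2, a receptor tyrosine kinase of the EGF receptor family, fell 6.02-fold, from 9.69 ± 0.18 to 7.10 ± 0.28, and Cd24a, a surface glycoprotein of epithelial cells, fell 11.8-fold. Ube2c was at 9.32 ± 0.29 against 10.23 ± 0.32. In limma, 430 of 23835 genes passed, 195 higher and 235 lower in recurrent cells, of which 155 and 111 differed at least 2-fold. With arrays centred on their medians 177 were higher and 323 lower, and quantile-normalized again 203 and 203. The arrays did not overlap for 9.02% of genes, where chance gives 2.86%. The count rested on each primary array, since 207 genes passed without primary 1, 225 without primary 2, 211 without primary 3 and 203 without primary 4.

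The 10 largest rises without overlap were those of Ogn, Postn, Aspn, Itgbl1, Mme, Dpt, Lum, Omd, Apod and Nkd2, with log2 fold changes from 6.97 to 4.16. Of these, Aspn, Itgbl1, Lum, Nkd2, Ogn and Omd started from a background level in primary cells, and among the falls Crct1, Mcpt8, Pilrb1, Serpinb2 and Slitrk6 ended at one (below 4.03 to 4.09, the 95th percentiles of olfactory receptor genes on the recurrent arrays). The rises of Mme (adjusted p = 3.5e-07) and Nkd2 (adjusted p = 1.18e-05) had the smallest p values. Apod, apolipoprotein D, at 4.26, was not called without primary 1 (adjusted p = 0.0588), primary 2 (0.0629), primary 3 (0.0677) or primary 4 (0.0661). The 10 largest falls included those of Slitrk6, Tmem45a, Crct1, Cd24a, Serpinb2, Pi15, Mcpt8, Htr1b and Pilrb1, from -4.14 to -2.97. Serpinb2 is an inhibitor of plasminogen activators, and Mcpt8 a protease of basophils, which fell from 6.81 ± 0.48 to 3.76 ± 0.78 (adjusted p = 0.00102). Pi15, at -3.21, was likewise not called without primary 1 (adjusted p = 0.0765), primary 2 (0.0522), primary 3 (0.0671) or primary 4 (0.0677).

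Fibroblast markers had 10 of 22 members higher and 12 not passing (13 higher and 1 lower adjusted over the list alone), with a median of 1.06 (adjusted p = 8.82e-18, and 0.0467 with an estimated correlation). Serpinf1 was at 12.23 ± 0.18 in recurrent and 9.12 ± 0.28 in primary cells (adjusted p = 6.58e-06), while Mgp, near the highest value of the table, differed by 0.03 (adjusted p = 0.932) and Fbn1, fibrillin 1, by 0.38 (adjusted p = 0.501). For matrix genes 10 of 45 rose (18 higher and 1 lower adjusted over the list alone, median 0.42, adjusted p = 1.07e-12, but adjusted p = 0.13 with an estimated correlation), among them Col3a1 at 3.90 and Fbln5 at 3.14. Of the TGF-beta genes 3 of 24 rose (7 adjusted over the list alone), namely Id3, Ltbp2 and Tgfb3 at 1.94, 1.44 and 1.28, with a list median of 0.42 (adjusted p = 1.05e-05, and 0.0467 with an estimated correlation). Genes of mesenchymal transition had 4 of 28 higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.00238, but adjusted p = 0.142 with an estimated correlation), including Mmp2 and Mmp9, gelatinases, at 2.21 and 1.36. In residual against primary cells, where its median of 0.21 was that of recurrent against primary cells, the list was not called (6 of 28 higher and 1 lower, 6 and 3 adjusted over the list alone, adjusted p = 0.195). It was with the values quantile-normalized again (0.0299), by fry (0.0351) and with arrays scaled to one interquartile range (0.00101).

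Among 25 growth factor receptor tyrosine kinases 3 rose, 2 fell and 20 did not pass (6 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.198, median -0.05, mean 0.30). Ddr2, a receptor for fibrillar collagen, rose by 3.32 (SE 0.42, adjusted p = 0.00198), Pdgfrb by 2.29 (adjusted p = 8.81e-06) and Egfr, the EGF receptor, by 1.82 (adjusted p = 0.00261). Erbb2 fell by 2.59 (SE 0.17, adjusted p = 2.33e-05). Met, the receptor of hepatocyte growth factor, did not have a common level in the recurrent group: it read 9.57, 9.63, 12.44 and 12.46 on recurrent 1, 2, 3 and 4, against 9.16 ± 0.24 in primary cells. Its neighbours on chromosome 6, in the gene order of assembly GRCm38.p6 and chosen after the Met values were seen, were high on the same arrays. On recurrent 3 Tes, Cav2, Cav1, Capza2 and St7 were 3.14, 3.04, 2.06, 2.78 and 4.03 above the primary mean, and on recurrent 4 Capza2, St7, Lsm8, Ing3 and Fam3c were 2.79, 4.27, 3.85, 3.11 and 2.66 above it.

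**Figure D3:**
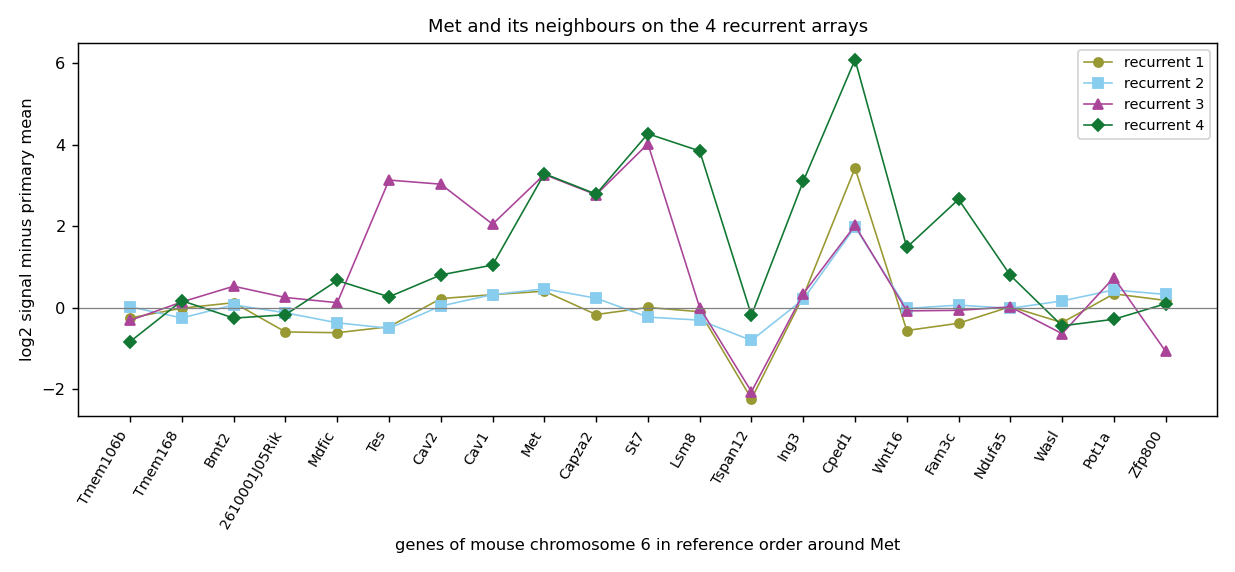
Difference of each recurrent array from the mean of the 4 primary arrays (y axis, log2 signal) for Met and its neighbours in reference order (x axis), 1 line per array. Besides Cped1, genes raised by more than 2 log2 units run from Tes to St7 on recurrent 3 and from Met to Fam3c on recurrent 4, with Tspan12 and Wnt16 between them at -0.18 and 1.49 and with Cav2 and Cav1 before Met at 0.81 and 1.05. Cped1 is raised on all 4 arrays, and recurrent 1 and recurrent 2 lie near 0 at Met, at 0.41 and 0.47.

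Canonical Wnt target genes were called with a median of 0.03 and a mean of 0.25 (adjusted p = 0.0296, but adjusted p = 0.214 with an estimated correlation), although 2 of 33 rose, 1 fell and 30 did not pass (6 and 1 adjusted over the list alone). Nkd2 rose by 4.16 and Lgr6 fell by 1.68 (adjusted p = 0.00599), and the list call was lost without primary 2 (adjusted p = 0.0616) or recurrent 2 (0.162) and by camera on ranks (0.177). Secreted Wnt inhibitors were called (median 0.22, adjusted p = 0.0274, but adjusted p = 0.142 with an estimated correlation). Of the 12 members 2 were higher and 1 lower (3 and 1 adjusted over the list alone), and the call was lost without primary 1 (adjusted p = 0.0518) or recurrent 1 (0.113) and by camera on ranks (0.134). Dkk2 rose by 2.02 and Sfrp2 by 1.29 (adjusted p = 0.00171 and 0.00698). Feedback genes of FGF and RAS-MAPK signalling were not called (adjusted p = 0.244, but 0.0448 without recurrent 1), with 1 of 24 higher and 2 lower (3 and 3 adjusted over the list alone). The member that rose was Spry1, an inhibitor of receptor tyrosine kinase signalling, at 2.24 (adjusted p = 0.000331).

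The G2/M and mitosis list stayed below primary cells by a median of -0.39 (adjusted p = 1.29e-09, but adjusted p = 0.142 with an estimated correlation). Of its 47 members 2 were lower, Bub1b and Tpx2, and 45 did not pass (12 lower adjusted over the list alone). Bub1b, a checkpoint kinase, changed by -0.89 and Tpx2, a spindle factor, by -0.86. Luminal markers were not called as a list (adjusted p = 0.306): Cd24a, Cldn3, a tight junction protein, and Areg fell, and 24 of 27 did not pass, with the same numbers adjusted over the list alone. Areg was not called without primary 1 (adjusted p = 0.0757), primary 3 (0.0812), primary 4 (0.0794), recurrent 3 (0.0637) or recurrent 4 (0.0551). Cldn3 fell by 2.19 (adjusted p = 0.00395), while Krt8 differed by -0.30 (adjusted p = 0.458). Mammary stem and progenitor genes were called lower (median -0.15, adjusted p = 0.0449, but adjusted p = 0.148 with an estimated correlation), with Cd24a and Lgr6 lower among 22 (3 lower adjusted over the list alone). That call was lost without primary 1 (adjusted p = 0.104), primary 3 (0.0530), recurrent 2 (0.0731), recurrent 3 (0.107) or residual 3 (0.0513), with arrays centred on their medians (0.0802), by camera on ranks (0.165) and with the dimmest genes left out (0.0707).

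Interferon response genes were called higher (median 0.40, adjusted p = 2.63e-05, but adjusted p = 0.353 with an estimated correlation), although 1 of 34 rose (5 higher and 1 lower adjusted over the list alone). Class I antigen presentation genes had a median of 0.51 (adjusted p = 1.95e-05, but adjusted p = 0.318 with an estimated correlation) and none of 15 passed in limma, also adjusted over the list alone. The mean of the interferon list was 5.62, 5.59, 6.63 and 6.22 on recurrent 1, 2, 3 and 4, and 5.54 to 5.67 on the primary arrays. That of the class I list was 7.13, 7.40, 8.15 and 8.19 on the same arrays, and 7.16 to 7.28 on the primary arrays. Chemokines and cytokines had 4 of 28 higher (7 adjusted over the list alone, adjusted p = 0.012, but adjusted p = 0.144 with an estimated correlation), a call that camera on ranks did not give (0.109), with Il34, a ligand of the macrophage growth factor receptor, at 1.38 (adjusted p = 0.0112). Macrophage and monocyte markers were called lower (median -0.40, adjusted p = 0.0274, but adjusted p = 0.628 with an estimated correlation), with 1 of 28, Cd14, lower (1 higher and 2 lower adjusted over the list alone). Without primary 1 (adjusted p = 0.0699), primary 2 (0.282), recurrent 1 (0.552) or recurrent 3 (0.134) the macrophage call was lost, as it was with arrays centred on their medians (0.0716). Cd14, which fell by 1.00, was not called without primary 1 (0.0830), primary 2 (0.0762) or primary 3 (0.0692).

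Further lists were called with few or no called members. In recurrent against primary cells these were lower for ribosome biogenesis and MYC targets (median -0.24), cholesterol synthesis (-0.50), glycolysis (-0.34), p53 targets (-0.39), S phase (-0.21), oxidative phosphorylation (-0.12), ribosomal proteins (-0.12), hypoxia targets (-0.14) and lysosome and autophagy genes (-0.12). Immediate early genes (0.38), pericyte markers (0.13), YAP and TAZ targets (0.22) and endothelial markers (0.16) were higher. On recurrent 1, 2, 3 and 4 the cholesterol synthesis mean was 5.99, 6.39, 7.09 and 7.15 (6.94 to 7.35 on the primary arrays). The glycolysis mean was 6.55, 6.85, 7.26 and 7.28 (7.27 to 7.47), and the hypoxia mean 6.92, 7.46, 8.02 and 7.86 (7.58 to 7.91). The falls of these lists were thus mainly those of recurrent 1 and recurrent 2. Members that passed were few: 3 of 22 YAP and TAZ targets rose and 1 fell (4 and 1 adjusted over the list alone), 1 of 24 immediate early genes rose (6), 1 of 9 pericyte markers (1) and 1 of 23 endothelial markers (1). Among the lower lists 2 of 43 ribosomal protein genes fell (5 adjusted over the list alone), 2 of 35 lysosome and autophagy genes (2 higher and 3 lower), 1 of 24 p53 targets (1 higher and 9 lower), 1 of 26 hypoxia targets (1) and none of 17 glycolysis genes (5), and the other 4 had none by either count. With an estimated correlation none of these 13 passed, with adjusted p from 0.13 to 0.552. Leaving out 1 array ended the call for oxidative phosphorylation (primary 2, adjusted p = 0.264), YAP and TAZ targets (recurrent 4, 0.0681), endothelial markers (primary 3, 0.0530, and recurrent 2, 0.222), hypoxia targets (primary 1, 0.0628, primary 3, 0.107, recurrent 1, 0.781, and recurrent 2, 0.0737) and lysosome and autophagy genes (primary 1, 0.0544, primary 2, 0.158, recurrent 1, 0.144, and recurrent 3, 0.0629). Quantile normalization ended it too for endothelial markers (0.0869), hypoxia targets (0.0825) and lysosome and autophagy genes (0.191). In all, 25 of 43 lists were called, 13 higher and 12 lower. Of these, fibroblast markers and TGF-beta genes kept their call with an estimated correlation, and the 18 lists not called had adjusted p from 0.110 to 0.863, with 6 of them differing in sign between median, mean and test. By fry the lists of endothelial and macrophage markers, interferon response, class I, immediate early, hypoxia, glycolysis, oxidative phosphorylation, cholesterol, ribosomal protein and lysosome genes were not called (adjusted p from 0.0750 to 0.485), and receptor tyrosine kinases were (0.0227). Hypoxia and lysosome genes were not called with the dimmest genes left out (0.0518 and 0.0555), nor hypoxia genes with arrays centred on their medians (0.0716). Of the settings chosen after seeing the data, scaling to one interquartile range ended the call of endothelial and macrophage markers, hypoxia, oxidative phosphorylation, ribosomal protein, lysosome and mammary stem genes (0.0555 to 0.318). The filter above olfactory receptor genes ended that of macrophage markers, hypoxia, lysosome and mammary stem genes (0.0726 to 0.118).

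The last comparison asked what changed between residual cells and recurrent tumour cells. Genes of mitosis rose in 45 of 47 cases (camera, adjusted p = 1.36e-83). Ube2c went from 5.13 ± 0.72 to 9.32 ± 0.29 (n = 3 and 4), Top2a, the topoisomerase of replicating cells, from 4.29 ± 0.83 to 8.53 ± 0.30, and Fosl1 from 4.74 ± 0.50 to 9.38 ± 0.43. Serping1 and Slc40a1, the iron exporter ferroportin, fell, the first from 8.94 ± 0.70 to 5.31 ± 0.88 and the second from 7.51 ± 0.36 to 3.50 ± 0.45. Dkk2 rose 10.4-fold, and Il1rl1, the receptor of interleukin 33, rose from 4.64 ± 1.03 to 9.03 ± 1.01. In limma, 1377 of 23835 genes passed, 854 higher and 523 lower in recurrent cells, of which 443 and 265 differed at least 2-fold. With the values quantile-normalized again 718 were higher and 575 lower, and with arrays scaled to one interquartile range, a setting chosen after seeing the data, 693 and 634. Fitted on these 7 arrays alone, without the primary arrays, 609 genes passed. The arrays did not overlap for 15.5% of genes, where chance gives 5.71%.

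The 10 largest rises without overlap were those of H2bc7, Fosl1, Anln, Lipg, Il1rl1, H2bc15, Top2a, Ube2c, H2ac4 and Rgs16, from 5.30 to 4.16. Lipg, endothelial lipase, rose by 4.49 (SE 0.37, adjusted p = 3.25e-05), and the 3 histone genes have near-identical copies. H2ac4, H2bc7, Lipg and Top2a started from residual means at a background level, and Scn7a and Slc40a1, among the falls, ended at one in recurrent cells. The 10 largest falls were those of Tspan8, Slc40a1, Fmod, Adamts16, Scn7a, Serping1, Hs3st1, Fam180a, Sprr1a and Cyp1b1, from -4.05 to -3.52. Tspan8, a tetraspanin of the mammary stem and progenitor list, read 8.09 to 8.94 on the residual arrays and 3.65 to 6.13 on the recurrent arrays (adjusted p = 0.000546). Hs3st1, which sulphates heparan sulphate, and Cyp1b1, a cytochrome P450, fell by 3.63 and 3.52 (adjusted p = 0.000384 and 0.00348). The call of Adamts16 was lost without residual 1 (adjusted p = 0.0507). Fitted on these 7 arrays alone, Adamts16 (0.0690), Sprr1a (0.0564) and Fam180a (0.143) were not called. The call of Fam180a was also lost without residual 1 (0.0871), residual 2 (0.119), residual 3 (0.102), primary 1 (0.0639), primary 2 (0.0599), primary 3 (0.0607), primary 4 (0.0610), recurrent 1 (0.0803), recurrent 2 (0.0510) or recurrent 3 (0.0914).

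Of the G2/M and mitosis list 45 of 47 rose and 2 did not pass (46 rose adjusted over the list alone), with a median of 2.56 (adjusted p = 1.36e-83, and 0.000948 with an estimated correlation). For S phase and DNA replication 35 of 44 rose and 9 did not pass (38 higher and 1 lower adjusted over the list alone), with a median of 1.21 (adjusted p = 6.26e-37, and 0.000948 with an estimated correlation). Mcm6 rose by 3.51 and Uhrf1 by 3.07. Ribosome biogenesis and MYC targets had 19 of 40 higher and 21 not passing (24 higher adjusted over the list alone), with a median of 0.58 (adjusted p = 2.4e-17, and 0.0438 with an estimated correlation), led by Dkc1 at 1.23 and by Nop58, a nucleolar protein, at 1.11. Ribosomal protein genes had 12 of 43 higher (19 adjusted over the list alone, median 0.59, adjusted p = 7.51e-11, but adjusted p = 0.112 with an estimated correlation), among them Rps26 at 1.40 (adjusted p = 0.00711). FGF and RAS-MAPK feedback genes had 11 of 24 higher and 13 not passing (14 higher and 1 lower adjusted over the list alone, median 0.75, adjusted p = 2.3e-09, but adjusted p = 0.112 with an estimated correlation), with Ccnd1 at 3.18 and Ereg at 2.69.

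**Figure D4:**
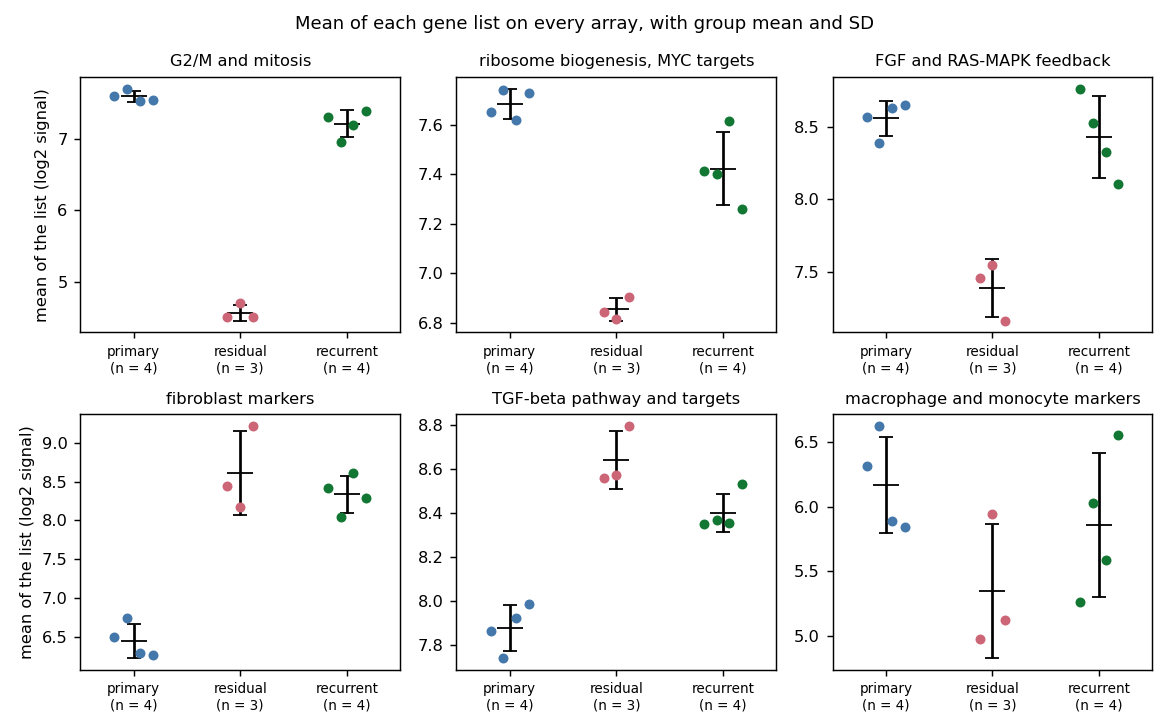
Mean log2 signal of the members of 6 gene lists on every array (points, y axis on a separate scale for each list), with the mean and SD of primary (n = 4), residual (n = 3) and recurrent (n = 4) arrays. The G2/M and mitosis list reads 4.51 to 4.70 on the residual arrays and 6.96 to 7.70 on the others, and fibroblast markers read 6.27 to 6.74 on the primary arrays and 8.04 to 9.21 on the others.

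Complement and acute phase genes were lower in recurrent than in residual cells, with 6 of 21 lower and 15 not passing (11 lower adjusted over the list alone, median -0.89, adjusted p = 6.92e-07, but adjusted p = 0.0621 with an estimated correlation). Cd59a, which blocks the membrane attack complex, fell by 1.39 (adjusted p = 0.0022). Luminal markers were called lower (median -0.58, adjusted p = 0.00442, but adjusted p = 0.311 with an estimated correlation). Of the 27 members 3 were higher and 5 lower (3 and 9 adjusted over the list alone). Krt8 and Areg, among its brightest members, went the other way and rose by 1.37 and 1.72, and the call was lost without residual 2 (adjusted p = 0.0727), the residual array with the highest mean of these markers. It was also lost with fry (0.0598) and (0.389) with a filter, chosen after seeing the data, that kept genes above the olfactory receptor genes on at least 3 arrays. Milk protein genes were called lower (median -0.17, adjusted p = 0.00493, but adjusted p = 0.0878 with an estimated correlation), with Csn2 at -3.16 and the mucin gene Muc15 at -1.84 lower among 16 (4 lower adjusted over the list alone). TGF-beta genes were called lower (median -0.35, adjusted p = 0.0233, but adjusted p = 0.176 with an estimated correlation). Of the 24 members 1 was higher and 5 lower (2 and 7 adjusted over the list alone), and the call was lost without residual 2 (adjusted p = 0.0515) or residual 3 (0.127) and by camera on ranks (0.0802). Tgfb1 fell by 1.48 and Smad6 by 1.54 (adjusted p = 0.00188 and 0.00142).

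Fibroblast markers were not called (median -0.05, adjusted p = 0.25, but 0.0398 without residual 2 and 0.0123 with arrays scaled to one interquartile range), with 1 of 22, Pi16, lower by 2.93 (2 lower adjusted over the list alone). Matrix genes missed the threshold (adjusted p = 0.0548) with 6 of 45 higher and 9 lower (6 and 13 adjusted over the list alone), and passed it as lower without residual 1 (0.0439), residual 2 (0.0125), recurrent 3 (0.0128) or recurrent 4 (0.00508). They also passed with arrays centred on their medians (0.0293), quantile-normalized again (0.00559) or scaled to one interquartile range (0.00249), and with either filter on dim genes (0.0238 and 0.00995). Lamb3, a laminin of epithelial basement membrane, fell by 2.88 (adjusted p = 0.000898). Canonical Wnt targets (2 of 33 higher, 3 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.716), secreted Wnt inhibitors (1 of 12 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.861) and receptor tyrosine kinases (4 of 25 higher, 4 and 4 adjusted over the list alone, adjusted p = 0.95) were not called. Nkd2 fell by 1.80, Ddr2 rose by 2.77 and Epha2, an ephrin receptor, rose by 1.51 (adjusted p = 0.00313, 0.00419 and 0.00123).

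Interferon response genes were called higher (median 0.58, adjusted p = 1.37e-07, but adjusted p = 0.327 with an estimated correlation). Of the 34 members 5 were higher (9 adjusted over the list alone). The list mean was 5.29 to 5.44 on the residual arrays, below each recurrent array, while the class I mean on recurrent 1, 7.13, was below that on residual 1, 7.21. The higher interferon genes included Irf1, an interferon-induced transcription factor, at 1.41 (adjusted p = 0.0059). Chemokines and cytokines had 6 of 28 higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 0.00442, but adjusted p = 0.112 with an estimated correlation), with Ccl5 and Ccl2, ligands that attract leukocytes, at 2.30 and 2.06. The neutrophil attractant Cxcl2 was at 2.19. Macrophage markers were called higher, at a median of 0.53 with none of 28 passing in limma, also adjusted over the list alone (adjusted p = 0.00111, but adjusted p = 0.682 with an estimated correlation, and 0.0573 without residual 1). Glycolysis genes had 5 of 17 higher (6 adjusted over the list alone, adjusted p = 4.4e-05, but adjusted p = 0.257 with an estimated correlation), with Tpi1 at 1.08.

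The remaining called lists were higher for class I antigen presentation (median 0.51), hypoxia targets (0.51), oxidative phosphorylation (0.26) and cholesterol synthesis (0.38), and lower for mammary stem and progenitor genes (-0.32) and lysosome and autophagy genes (-0.16). Of 15 class I genes 1 rose (3 adjusted over the list alone), of 26 hypoxia targets 4 rose and 1 fell (9 and 3), of 57 oxidative phosphorylation genes 1 rose (1), of 23 cholesterol synthesis genes 3 rose and 2 fell (4 and 3), of 22 mammary stem genes 1 rose and 4 fell (1 and 6), and of 35 lysosome and autophagy genes 1 rose and 5 fell (3 and 12). With an estimated correlation these 6 had adjusted p from 0.112 to 0.682. The cholesterol call was lost without recurrent 3 (adjusted p = 0.0852) or recurrent 4 (0.124), and the mammary stem call without residual 2 (0.0537). Settings chosen after seeing the data ended the cholesterol call, with the filter above olfactory receptor genes (0.104), and the oxidative phosphorylation call, with arrays scaled to one interquartile range (0.130). In all, 19 of 43 lists were called, 13 higher and 6 lower, and 24 were not, with adjusted p of at least 0.0548 and 9 of them differing in sign between median, mean and test. By fry the lists of macrophage markers, interferon response, class I, hypoxia and cholesterol genes were not called (adjusted p from 0.0780 to 0.342), and pericyte (0.0212) and lymphocyte and natural killer cell markers (0.0190) were. Camera on ranks did not call mammary stem genes (0.0777).

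Taking the comparisons in sequence, 1078 genes reverted: 359 were higher in residual than in primary cells and then lower in recurrent than in residual cells, and 719 were lower and then higher. Independent lists of these sizes would share 25.1 and 65.0 genes, and simulated unchanged groups with the same residual arrays shared 0 and 0.01 on average. Almost no gene is called in unchanged groups, so they do not show how much sharing the residual arrays adds. The residual arrays were not split, and that part was not measured. Fmod and Serping1 were in the first set, and Ube2c, Fosl1 and Ccnd1 in the second. Fitted 2 groups at a time, 541 genes reverted. Other genes stayed apart from primary cells at both stages: 140 were higher in residual and in recurrent cells, Postn, Ogn and Nkd2 among them, and 157 were lower, with Erbb2, Htr1b and Lgr6 among them. Independent lists would share 9.38 and 17.9 genes, and simulated unchanged groups against the same primary arrays 0 and 0.01, again with almost no gene called. With the primary arrays split so that each comparison used 2 of them, 43 to 53 genes were higher and 36 to 40 lower in both, where independent lists would share 1.33 to 1.66 and 2.47 to 3.08. The covariance of the fold changes against primary cells was 0.142, against 0.0236 in simulated unchanged groups, and 0.116 to 0.129 with split primary arrays.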

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

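The tests of fibroblast and matrix genes, of the Met neighbourhood and of signal range were chosen only after those results had been seen, and the tests of splits were not.

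Fibroblast and matrix genes were higher in residual and recurrent cells, with fibroblast list medians of 2.33 and 1.06 against primary cells (with an estimated correlation, adjusted p = 0.0639 and 0.0467, and 0.113 and 0.13 for matrix genes). The cells had been isolated by their tumour label, a sort that should remove unlabelled host cells. Macrophage markers still averaged 6.17 in primary cells, above the background bound of 4.05, so some host cells may have passed the sort. A lower share of tumour cells that raises every other cell type alike would raise the macrophage list in residual cells. Its median there was -0.90 (camera, adjusted p = 0.403 with an estimated correlation). The list mean was 4.98 to 5.94 on the residual arrays and 5.84 to 6.62 on the primary arrays (6.17 on average), so the groups overlapped. The list did not rise with the fibroblast list, which argues against this explanation in residual cells, though only weakly given the overlap. In recurrent cells it stays open, since the macrophage median was -0.40 with 1 of 4 arrays above the primary mean, and endothelial genes lay near background. The endothelial list was called higher there (camera, adjusted p = 0.0289, but 0.331 with an estimated correlation), with 1 of 23 members higher. Cdh5, an endothelial cadherin named outside the rule, read 10.13 on recurrent 3, and 4.97, 5.09 and 4.66 on recurrent 1, 2 and 4. Admixed host fibroblasts of one profile would keep their genes in one ratio, and the SD left over the recurrent arrays after gene and array effects was 0.740 for 8 genes at least 3 log2 units above primary cells, against 0.507 over the primary arrays, a ratio of 1.46 that leaves this explanation open. A change of the tumour cells themselves, by stage, may also account for it and was not tested. Already in primary cells 16 of 22 markers and 39 of 45 matrix genes were above the background range, with Mgp at 12.98 ± 0.04. Tumour cells, or host cells that passed the sort, could give such levels.

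Met, Capza2 and St7 read higher on recurrent 3 and recurrent 4 than on the other 9 arrays. A change of Met alone is argued against by its neighbours, since the other 4 genes of the best window of 5 genes at Met had a median 2.91 above the primary mean on recurrent 3 and 3.32 on recurrent 4. A gain of the chromosome segment may explain this and stays open. Met ranked 14 of 12073 genes by this measure on both arrays (0.116%), just outside the bound of 0.1% set for it. That rank counts genes, and the neighbours of Met share its windows, so missing the bound does not count against a gain. Windows near Ippk, beside Ogn, Omd and Aspn, ranked first on all 4 recurrent and all 3 residual arrays, so high windows also arise without Met. The window of 5 genes was chosen after a wider running median had been looked at, and no DNA was measured.

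Cell cycle genes were lower in residual cells, whose arrays had a narrower signal range, as were ribosomal protein genes, whose call was lost with an estimated correlation (adjusted p = 0.0982). That range as the whole cause is argued against by 10000 random lists matched on the primary mean, whose lowest median was -0.51 against -3.04 for the G2/M list and -0.44 against -0.76 for ribosomal proteins. The random genes were drawn singly, while members of these lists vary together (estimated correlation 0.18 for ribosomal proteins). The narrower margin for ribosomal proteins is therefore weaker. After arrays were scaled to one interquartile range the G2/M median was -3.07. A change by stage, such as fewer dividing cells, may account for it and was not tested apart from the groups.

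Other splits of the same arrays were counted. The count of called genes was reached by the real split alone, 1 of 35, in each comparison (2960 against at most 4 in other splits for residual against primary, 430 against 0 for recurrent against primary, and 1377 against 18 for recurrent against residual). A share of 1 of 35 is the smallest these splits can give. Other splits mix the groups, which widens the spread, so few calls were likely in them. The labels do not say whether arrays came from separate animals, so chance between animals is not excluded. For reverting genes 1 of 100 drawn regroupings of the 11 arrays, the real one, reached 1078, and the highest other, 882, had kept all 3 residual arrays together as the residual group, a structure of the samples. For called lists, 3 of 35 splits of residual and primary arrays gave as many as the real 17, and the highest other also gave 17, so chance cannot be excluded for that count. The real split alone reached the count for recurrent against primary cells (1 of 35, 25 against 17) and for recurrent against residual cells (1 of 35, 19 against 17). This is the smallest share possible and does not exclude chance.

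Single arrays stood far from the other 3 of their group in 23 of 432 tests of a gene or list mean in a group of 4 (5.32%), where chance gives about 1 in 20. Primary 2 held 8 of them. There Cdh2 read 7.88 against 8.40 to 8.42 on the others, Lgr6 7.85 against 8.24 to 8.27, Met 8.81 against 9.23 to 9.31, H2ac4 7.66 against 6.65 to 6.76 and Nop56 8.92 against 8.64 to 8.69. Its list means were 9.10 against 9.58 to 9.67 for immediate early genes, 9.70 against 9.42 to 9.44 for oxidative phosphorylation and 7.27 against 7.09 to 7.11 for fatty acid oxidation. On primary 4 Clu read 10.05 against 9.73 to 9.78 and Sfrp1 7.22, below the other 3. Rgs16 read 9.45 on primary 3 against 9.82 to 9.89, and the Wnt ligand mean was 4.00 on primary 1 against 4.07 to 4.08.

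On recurrent 1 Ccl8 read 6.82 against 7.85 to 7.92 on the other recurrent arrays, Igf1r 7.68 against 7.09 to 7.15, and fatty acid oxidation genes 7.23 against 7.10 to 7.12. Cyc1 read 8.44 on recurrent 2 against 8.78 to 8.78. On recurrent 3 Mfap5 read 10.15 against 7.16 to 7.24, Omd 5.22 against 7.09 to 7.45, Rps26 10.42 against 9.38 to 9.47, and the ribosomal protein mean 7.57 against 7.10 to 7.11. On recurrent 4 Rps23 read 4.17 against 6.09 to 6.34, the pericyte mean 4.64 against 4.54 to 4.55, and the TGF-beta mean 8.53 against 8.35 to 8.37.

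Among 642 probe sets without a gene name, which no comparison above used, 33 passed in limma for residual against primary cells (21 higher and 12 lower, 5.14% against 12.3% of named genes), 2 for recurrent against primary cells (1 and 1, 0.312% against 1.80%) and 15 for recurrent against residual cells (6 and 9, 2.34% against 5.71%).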

How the results depend on the processing

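Scaling to one interquartile range and the filter by olfactory receptor genes were alternatives chosen after the data had been seen, and all others were planned. Of 241 results of named genes 177 kept their direction and call under every alternative, 64 lost or gained a call under at least 1 (52 of them under an alternative other than leaving out an array), and 0 reversed. Of 129 list results 55 kept both and 74 did not (71 outside leaving out an array). The unfolded protein response list in residual against primary cells reversed: its median was -0.05 (adjusted p = 0.589), and 0.12 (adjusted p = 0.0176) after scaling to one interquartile range, with adjusted p from 0.0176 to 0.926 over its alternatives, and the cause was not tested. Signal near background limits all of this for dim genes.

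With an estimated correlation 4, 2 and 3 lists were called in residual against primary, recurrent against primary and recurrent against residual cells, in place of 17, 25 and 19, and fry called 23, 15 and 15. The cause was not tested. Pericyte markers and milk protein genes lost their calls in residual against primary cells with estimated correlations of -0.08 and -0.002, below the preset of 0.01. Members that vary together do not account for the loss of those calls. Fitted on only the groups compared, 3165, 345 and 609 genes passed in these comparisons, in place of 2960, 430 and 1377, and 541 reverted. The first count rose, so fewer arrays alone do not account for the falls. At least a 2-fold change left 1361, 266 and 708 called and 542 reverting genes, and an adjusted p under 0.01 left 1375, 142, 521 and 440, by construction. Leaving out each array in turn gave 2228 to 3073 genes in residual against primary cells, 203 to 420 in recurrent against primary cells, 936 to 1325 in recurrent against residual cells, 784 to 970 reverting genes, and 15 to 18, 20 to 25 and 18 to 19 lists. Centring arrays moved the median of all genes by -0.08, -0.05 and 0.03.

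With the replicate number as a block 2198, 277 and 872 genes were called and 705 reverted, and 17, 25 and 20 lists were called. Arrays with the same number had correlations of -0.08 to 0.02 between their deviations from the group means, so the numbers give no sign of pairing.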

Other observations

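The clustered protocadherin beta genes were chosen only after their values had been seen, and were not tested as a list. These neuronal adhesion genes lie in a row on one chromosome and share sequence, so their signals may not be separate. Of 22 measured Pcdhb genes 11 rose in residual against primary cells (median 1.16), 1 rose in recurrent against primary cells (median 0.45) and 6 fell in recurrent against residual cells (median -0.62). Their mean was 3.43 to 3.76 on the primary arrays, 4.44 to 5.19 on the residual arrays and 3.83 to 4.29 on the recurrent arrays. For olfactory receptor genes the medians were 2.33 to 2.54 and the 95th percentiles of single genes 3.96 to 4.38. The Pcdhb means lay above those medians on every array, and above the 95th percentiles (4.34 to 4.38) on the residual arrays.

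Several lists were called in none of the comparisons in the main fit. FGF ligands and receptors passed in recurrent against primary cells under an alternative, with a lowest camera adjusted p of 0.0378. In residual against primary cells the medians were 0.07 for Wnt ligands (adjusted p = 0.483), 0.09 for FGF ligands and receptors (0.154), 0.13 for adipocyte markers (0.106, but 0.0431 without residual 3), 0.07 for neutrophil and mast cell markers (0.712), -0.03 for fatty acid oxidation (0.712) and 0.13 for fatty acid synthesis (0.904). Markers of red blood cells and of skeletal muscle were at medians of 0.13 and 0.11 (0.523 and 0.712). In residual against primary cells the neutrophil and mast cell list had a mean of -0.32, opposite in sign to its median. Of its 16 members 1 was higher and 1 lower. S100a8, named outside the rule, read 11.51 to 12.03 on the primary arrays and 7.09 to 8.49 on the residual arrays. On recurrent 1, 2, 3 and 4 it read 11.81, 10.51, 6.04 and 4.34.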
